A study of Homo sapiens with 14 samples.

How the data were processed

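CUT&Tag maps where a protein or histone mark sits on chromatin by tethering the Tn5 transposase to an antibody, so that nearby DNA is cut and tagged for sequencing. The 14 libraries came from Jurkat, an established human T cell line derived from a T cell acute lymphoblastic leukaemia. Per the labels, cells carried a lentiviral control shRNA (shCtrl) or an shRNA against SATB1 (shSATB1). The groups were SATB1 in shCtrl (2 libraries), H3K27ac in shCtrl and in shSATB1 (2 each), CTCF in shCtrl and in shSATB1 (3 each) and Matrin 3 (2, with no shRNA on the label). Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

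Each library came with 1 peak list, called per sample. The deposited columns are position, total signal and maximum signal of each peak, that is, coverage summed over the peak and its highest value, as whole numbers with no scaling recorded by the authors. Per the submitters' processing notes, Trim Galore, Bowtie2, SAMtools, deepTools and SEACR were used, with MACS2 for all but the Matrin 3 samples, and the genome build was GRCh38. Versions, the alignment filter and any control library were not given in the sources used here. The names of the SATB1 lists carry a threshold of 0.007. Read totals were not used here, so the depth of each library is unknown. The lowest total signal in a list is given as a description of where its calling stopped. Peak signal was used to describe, rank or filter peaks within a list. The planned stricter threshold was the exception: it set 1 limit on the unscaled signal of both arms, and its values are not reported.

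Peaks on chromosomes 1 to 22 and X were kept. The 405 others, 0.148% of 273747 deposited peaks, were left out. Peaks of the libraries compared were merged into regions where they shared at least 1 bp, and a region was called in a library if a peak of that library overlapped it. SATB1 regions were those called in both SATB1 lists, CTCF regions of the control arm those in at least 2 of 3 lists, and H3K27ac regions those in both. Overlaps were set against 100 circular shifts of the regions along each chromosome (one-sided permutation test). Library values were compared between arms by two-sided exact permutation tests, whose smallest p is 0.1 with 3 against 3 and 0.333 with 2 against 2, so neither can pass 0.05. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 17 lists (289 distinct genes, 294 memberships, each matched in the gene table). Shares of regions carry 95% Wilson intervals, which cover counting error only.

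Genes were the 19974 protein-coding genes of the RefSeq GRCh38.p14 table on those chromosomes. Groups, lists, planned tests and the rule for named genes were fixed before the data were examined. The plan did not name the Fisher's exact tests over lost and gained regions, among them the SATB1 share of H3K27ac regions. Nor did it name the count of genes that lost CTCF at an end or the tests of lists for loss. The plan placed SATB1 at a gene by the annotated 5′ end. The gene table used here gives no strand, so either annotated end within 2 kb was used instead, and exons and introns were not told apart. The planned search for the CTCF motif needed genome sequence and was not run. The named genes were drawn from the 10 with SATB1 at an end and the highest mean percentile of maximum signal; the 10 highest-ranked regions per direction for CTCF and H3K27ac, 1 per gene, named by an overlapped or else the nearest gene; listed genes that lost or gained CTCF or H3K27ac at an end in all libraries of an arm; SATB1 itself; and up to 4 members per list with SATB1 at an end. Other genes named were chosen after their values were seen.

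Alternatives were another overlap rule, lists cut to equal length, windows of 500 bp on the peak maxima, bins of 1 kb, other gene windows and backgrounds, stratification by rank, leaving out each library, and the replicate number as a block. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated CTCF lists made from 34146 regions, 84.5% of 200 planted losses and 90.5% of 200 planted gains were recovered, with 2 and 1 regions called that were not planted. On simulated H3K27ac lists from 20526 regions the shares were 88.5% and 91.5%, with 39 and 40 unplanted calls. In these simulations every library called unplanted regions at the same high rate. The real CTCF shSATB1 lists called 38.5%, 47.1% and 53.6% of merged regions. The real H3K27ac lists called 83.2% and 79.8% in shCtrl and 80.4% and 70.6% in shSATB1, also below the simulated rate. The simulations therefore do not estimate false losses or gains in the real lists. A planted overlap of 30% was recovered as 30%, and a planted gene list among 19974 genes was called in 97% of 100 simulations, with 2 calls of other lists. Positions are 1-based.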

Results

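SATB1, a chromatin organiser abundant in T cells, was mapped in Jurkat cells together with CTCF, which marks insulator and loop-anchor sites, with H3K27ac, a mark of active promoters and enhancers, and with Matrin 3, a nuclear matrix protein. CTCF and H3K27ac were mapped with and without SATB1 knockdown. The series asks how SATB1 relates to chromatin around CTCF sites. The lists held 15210 and 14726 peaks for SATB1, 17863 and 17141 for H3K27ac in shCtrl, and 17925 and 15972 for H3K27ac in shSATB1. CTCF lists held 31270, 31141 and 32540 peaks in shCtrl and 14695, 17904 and 20284 in shSATB1. The Matrin 3 lists differed widely, with 24566 and 2105 peaks. The lowest total signal of a called peak was 13359 to 14792 in the CTCF shCtrl lists and 6017 to 7332 in the CTCF shSATB1 lists, in the authors' signal, which was not scaled between libraries.

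**Figure D1:**
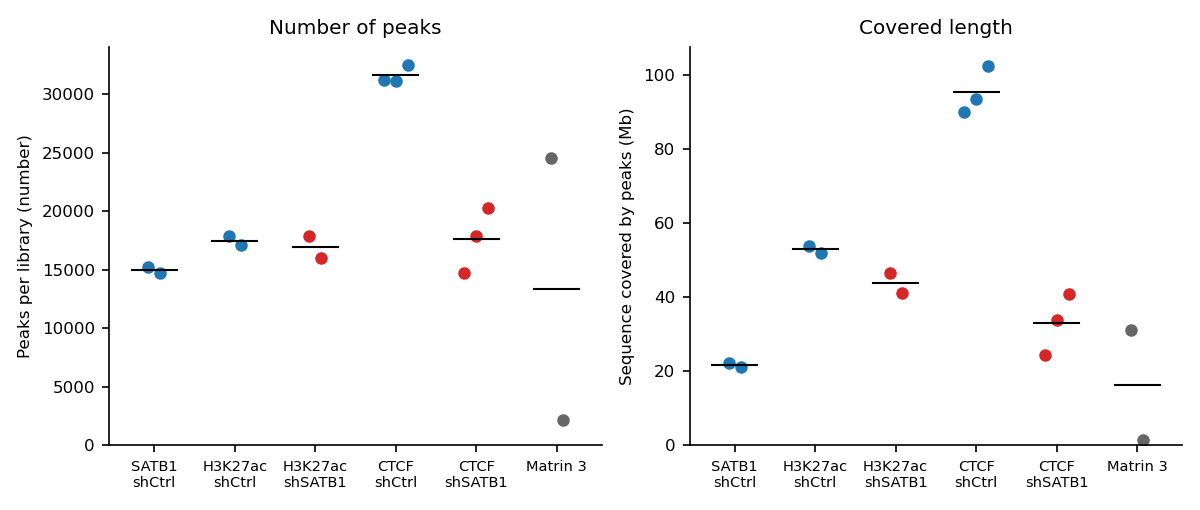
Peaks per library (left, number) and sequence covered by them (right, Mb) for each group; each point is a library, lines are group means, blue is shCtrl, red is shSATB1 and grey is Matrin 3. The 3 CTCF shSATB1 libraries lie between 14695 and 20284 peaks, below all CTCF shCtrl libraries.

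At the SATB1 gene itself (chromosome 3, 18345377 to 18445592, GRCh38) H3K27ac peaks covered 38.7 and 35.4 kb in the shCtrl libraries and 40.9 and 35.6 kb in the shSATB1 libraries. CTCF peaks there numbered 4 in each shCtrl library and 2, 1 and 3 in the shSATB1 libraries. SATB1 peaks over its own gene covered 35.1 and 36.1 kb in the control lists. Peak lists do not measure SATB1 transcript or protein, so they do not check the knockdown.

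SATB1 regions mostly overlapped H3K27ac, CTCF and the longer Matrin 3 list. Of 13072 SATB1 regions, 75.3% (95% interval 74.6 to 76.0) overlapped H3K27ac, against 2.79% ± 0.180 (SD over 100 shifts) after circular shifts. The overlap with CTCF was 71.0% (70.2 to 71.8), against 5.94% ± 0.282 after shifts. Regions called in both Matrin 3 lists overlapped 11.5% of SATB1 regions, and 4.56% of those more than 2 kb from gene ends, against 0.201% ± 0.0384 after shifts of all. The longer Matrin 3 list overlapped 82.9% (82.2 to 83.5) of SATB1 regions, against 2.37% ± 0.173. H3K27ac, CTCF and that Matrin 3 list together overlapped 7789 SATB1 regions (59.6%), while 1189 (9.10%) overlapped none of them. The permutation p was 0.00990 for each overlap, the smallest that the shifts can give. CTCF regions also overlapped H3K27ac far above shifts, at 39.5% against 4.07%. The shifts do not keep regions within open chromatin, and no control library was used here. Signal from open chromatin shared by all targets was therefore not told apart from binding.

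SATB1 regions had a median width of 1364 bp. Gene ends lay within 2 kb of 4250 of them (32.5%, 31.7 to 33.3), against 6.60% ± 0.317 after shifts; 39.1% lay elsewhere inside genes and 28.4% outside genes. The lists shared the exact start of 6009 peaks, 40.8% of the shorter list, while none of the other 90 pairs of lists shared more than 1.03%. The SATB1 lists were therefore counted as 1 sample, and no spread between them is given.

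Among single genes, the highest SATB1 peaks lay at the ends of WDR74 (chromosome 11, 62832905 to 62841809) and TAF12 (chromosome 1, 28602850 to 28648269), both at a mean within-list percentile of 99.95. RNF169, RTKN2, VANGL1, NOP14, GRK4, MND1, CALR and ATP2C1 followed, down to a percentile of 99.7. NOP14, a ribosome biogenesis factor, and GRK4 are neighbours on chromosome 4 and share the region. CALR encodes calreticulin, a calcium-binding chaperone of the endoplasmic reticulum.

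T cell genes carried SATB1 at their ends more often than other genes. A SATB1 region lay at an end of 4918 of 19974 protein-coding genes (24.6%), but at 13 of 20 T cell receptor signalling genes (adjusted p = 0.00131, Fisher's exact test), 11 of 16 thymocyte coreceptor and recombination genes (0.00139) and 11 of 20 T-lineage transcription factor genes (0.0117). Genome architecture genes stood with them, at 16 of 24 (adjusted p = 0.000276, Fisher's exact test). Immediate-early genes and apoptosis genes each had SATB1 at 10 of 20 (adjusted p = 0.0386 for both, Fisher's exact test). Both lost the call with a 1 kb window (adjusted p = 0.220 and 0.0817, Fisher's exact test), over whole gene bodies (0.0703 and 0.152) and against genes within 100 kb of a peak (0.0942 for both, where the odds ratio was 2.73 in place of 3.07). Without SATB1 replicate 1 the apoptosis list had an adjusted p of 0.0556 by the same Fisher's exact test. None of these lists kept its call among genes with H3K27ac at an end in both shCtrl lists, of which 57.7% carried SATB1 against 3.70% of genes without it. In that background the T cell receptor list had SATB1 at 13 of 16 (81.3%, odds ratio 3.19, adjusted p = 0.634, Fisher's exact test), the thymocyte list at 11 of 12 (91.7%, odds ratio 8.10, p = 0.0178, adjusted 0.303), the transcription factors at 10 of 14 (adjusted p = 1) and genome architecture at 16 of 22 (0.831). Fewer members were tested there, and the thymocyte list alone had an unadjusted p under 0.05. The apoptosis list turned direction, at 46.7% against 57.7% of the other genes.

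Within the T cell receptor list, SATB1 lay at CD2 (percentile 93.6), CD3E, a receptor chain (88.7), and FYN (85.5). TOX (92.9), LEF1 (92.0) and BCL11B (90.6), regulators of T cell development, and RUNX1 (70.0) led the transcription factors. CD1B (95.8) and CD1C (93.8), lipid-presenting molecules of cortical thymocytes, led the thymocyte list, followed by ARPP21 (85.4) and DNTT (75.7), the terminal transferase of V(D)J recombination. The architecture list was led by the CTCF gene (97.4), CHD4 (97.4), the lamin gene LMNB1 (87.0) and LBR (86.5). JUN (98.6), JUND (76.9), DUSP2 (75.1) and EGR2 (65.5) led the immediate-early genes, and CASP8 (87.0), FAS (87.0), BAK1 (82.1) and CASP9 (80.7) the apoptosis genes.

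None of the 26 clustered protocadherin genes carried SATB1 (adjusted p = 0.00409, Fisher's exact test). The test counted these clustered genes as independent, so its p ignores that neighbours can share a site. Lists of TAL1-complex and leukaemia oncogenes (7 of 20, with LMO2 at percentile 91.4, LDB1 at 80.7, LMO1 at 79.8 and MYC at 79.0), cytokines and their receptors (8 of 22, with IL2 at 88.4, IL2RG at 73.9 and IL7R at 51.0) and ribosomal proteins (7 of 20, with RPL3 at 86.6, RPS19 at 77.1, RPL7 at 74.97 and RPL27 at 48.9) did not pass the test. Markers of other lineages did not either. B cell markers had SATB1 at 2 of 12 (IGLL1 at 89.2, CD79A at 40.3) and myeloid markers at 2 of 14 (CEBPE at 18.6, CSF3R at 15.7). Erythroid and megakaryocyte markers had it at 2 of 12 (EPOR at 90.4, TFRC at 25.1). Neuronal markers had it at 2 of 12 (SNAP25 at 46.3, DLX2 at 40.3), and epithelial and stromal markers at 1 of 12 (COL1A1 at 34.7). The HOXA cluster had SATB1 at 1 of 11 genes, HOXA3. MHC class I genes had it at 0 of 13, but 12 of these had no peak at a gene end in any of the 14 lists, so the lists say little about them. The MHC class I, HOXA, protocadherin, epithelial and neuronal lists had no gene with H3K27ac in both shCtrl lists and were not tested in that background.

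**Figure D2:**
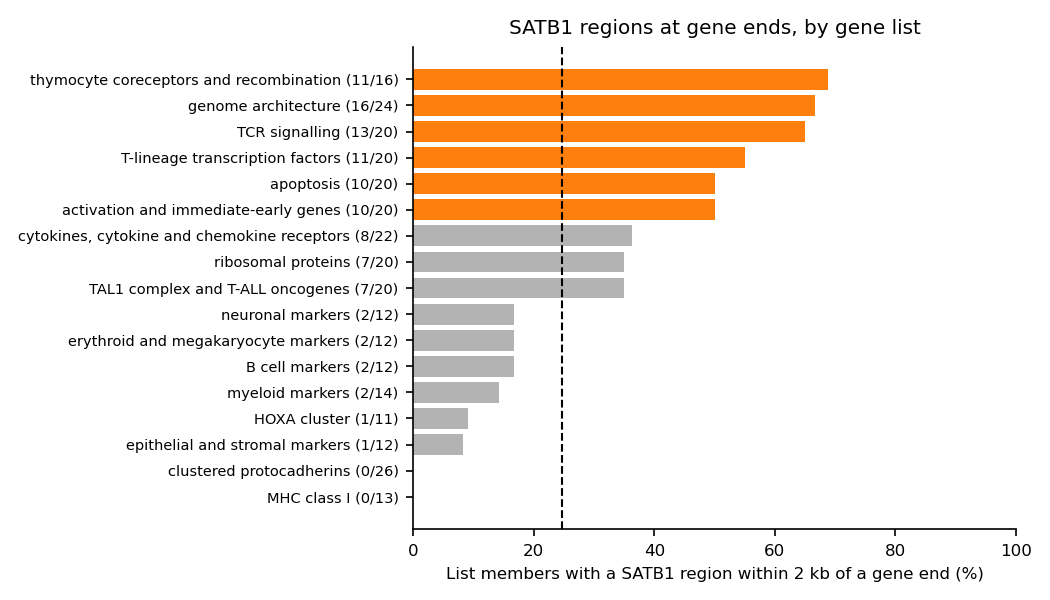
Share of each list's members with a SATB1 region within 2 kb of a gene end (x axis, percent), with members carrying SATB1 over all members in brackets; orange bars have an adjusted p under 0.05, and the dashed line is the share of all protein-coding genes, 24.6%. The protocadherin list, at 0 of 26, lies below the line and also passed the test.

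CTCF lists were shorter after SATB1 knockdown, and regions that differed were mainly losses. Peaks numbered 31650 ± 773 (SD, n = 3) in shCtrl and 17628 ± 2805 (n = 3) in shSATB1, and the length they covered was 95.4 ± 6.42 Mb and 33.0 ± 8.20 Mb (exact permutation p = 0.1 for each, the smallest that 3 against 3 allows). The number fell by 44.3%. Of 34146 merged regions, 12184 were called in all 6 libraries, 7747 in every shCtrl library and no shSATB1 library, and 3 in the reverse. With all lists cut to the 14695 highest peaks, the counts were 598 and 214. In windows of 500 bp on the peak maxima they were 7528 and 422, and in bins of 1 kb 33277 and 9. The gained regions numbered 14 without shSATB1 replicate 1 and 6 without shSATB1 replicate 2. Library depth was not given in the sources used here, so the counts were not corrected for it.

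Lost CTCF regions lay at gene ends and active marks less often than regions called in all libraries. Gene ends lay within 2 kb of 24.5% (95% interval 23.5 to 25.4) of the lost regions and 56.9% (56.0 to 57.7) of those called in all 6 libraries. H3K27ac overlapped 30.0% and 52.9%, the longer Matrin 3 list 37.2% and 67.1%, and SATB1 16.4% (15.6 to 17.3) and 40.4% (39.6 to 41.3). Lost regions were also narrower, with a median of 2603 bp against 4087 bp. With equal list lengths, gene ends lay at 35.3% of lost, 34.6% of gained and 59.9% of regions called in all libraries (gained against lost p = 0.868, Fisher's exact test over regions). By the same Fisher's exact test, gained regions then carried SATB1 (31.8% against 18.2%, p = 6.91e-05), H3K27ac (45.3% against 31.6%, p = 0.000444) and gene bodies (73.8% against 62.04%, p = 0.00195) more often than lost ones, while Matrin 3 (51.9% against 46.2%, p = 0.152) did not pass. Lost regions ranked low in the shCtrl lists, at a median percentile of 27.9 against 79.5 for regions called in all libraries.

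The highest-ranked lost regions were inside LOC102724250 (chromosome 1, 633954 to 634114, 161 bp, percentile 94.4 ± 0.508, SD, n = 3) and KYNU, which encodes a tryptophan-degrading enzyme (chromosome 2, 143034081 to 143035460, 84.5 ± 1.07), and at an end of POLR2J, an RNA polymerase II subunit gene (chromosome 7, 102478369 to 102479279, 84.1 ± 4.07). CAMTA1, CXCL3, CLUL1, DAGLB and CMC1 followed, with regions 164 kb from AADAT and 37.0 kb from AGBL1. Of these 10, CMC1 alone overlapped SATB1. The LOC102724250 region was narrow beside the median of 2603 bp for lost regions. No filter for regions prone to artefact signal was applied here, so whether it is a CTCF site was not tested. The 3 gained regions were inside STIM1 (chromosome 11, 4006937 to 4008522), BRD7 (chromosome 16, 50318737 to 50321005) and FAM149B1 (chromosome 10, 73217938 to 73219628), at percentiles of 8.47 to 12.05.

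At genes, 1714 of the 11580 with CTCF at an end in every shCtrl library had it in no shSATB1 library, and 0 showed the reverse. With lists of equal length, 325 genes had lost it. The lost genes included the leukaemia genes TAL1, LMO2, TCF12 and PHF6; PTCRA, the pre-T cell receptor alpha chain; IL10 and CCR4; NFKB1 and FOS; BIRC5 and BAX; HOXA10 and HOXA11; RPL37, RPL30 and RPS6; the B-lineage genes BLK, POU2AF1, VPREB1 and IGLL1; the myeloid genes S100A9 and SPI1; and SYP. Of these, LMO2, PTCRA, IL10, NFKB1, RPS6 and IGLL1 carried SATB1.

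CTCF calls at gene ends fell across most lists. Over all protein-coding genes, 11989, 12065 and 12289 had CTCF at an end in the shCtrl libraries and 7932, 8966 and 9485 in the shSATB1 libraries, and 15 of the 17 lists had fewer members with CTCF on average in shSATB1. Ribosomal protein genes went from 19 in each library to 15 in each, and apoptosis genes from 18 in each to 14.3 ± 1.53 (SD, n = 3; exact permutation p = 0.1 for each). T cell receptor signalling had CTCF at 17.7 ± 0.577 members (SD, n = 3) in shCtrl and 16.3 ± 0.577 in shSATB1 (exact permutation p = 0.2), and 0 of its 17 genes called in every shCtrl library were lost (p = 0.160, adjusted p = 0.679, Fisher's exact test). B cell markers went from 6.67 ± 0.577 to 1.33 ± 0.577 members, the TAL1 list from 11.7 ± 0.577 to 7 in each library, cytokines from 13.0 ± 1.73 to 6.67 ± 1.15, and the HOXA cluster from 7 in each library to 3.33 ± 1.15 (exact permutation p = 0.1 for each). Among genes with CTCF in every shCtrl library, 4 of 6 B cell markers were lost against 14.8% of the others, which did not pass correction over the lists (p = 0.00559, adjusted p = 0.0950, Fisher's exact test). No other list had an unadjusted p under 0.05, and no list passed. Protocadherins had 7 members called in every CTCF library but shSATB1 replicate 1, which had 1.

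CTCF regions that carried SATB1 were called more often than others in the shSATB1 libraries. SATB1 overlapped 8270 of the CTCF regions called in at least 2 libraries and not the other 22059. In shCtrl, 97.8% ± 0.841 (SD, n = 3) of the SATB1-bound and 95.6% ± 1.81 of the other regions were called. In shSATB1 the shares were 69.8% ± 7.59 and 45.6% ± 8.78. The gap between them was 2.22 ± 1.14 percentage points in shCtrl and 24.2 ± 1.24 in shSATB1 (exact permutation p = 0.1, smallest possible). The shCtrl shares were near their ceiling by the choice of regions, and SATB1-bound regions ranked higher, so a general fall in calls alone would widen the gap. Compared within deciles of peak rank, the gaps were 1.14 ± 0.725 and 10.6 ± 0.911, and with equal list lengths they differed by 7.55 points in place of 21.96. Among regions called in all 6 libraries, the rank advantage of SATB1-bound regions was 15.5 ± 0.434 percentile points in shCtrl and 15.6 ± 0.141 in shSATB1 (exact permutation p = 0.8), a difference of 0.0999. It was −0.498 and −0.371 without shCtrl replicates 2 and 3, and −0.824, −1.27 and −0.786 without shSATB1 replicates 1, 2 and 3. These tests cannot go below 0.1, and regions called in all libraries leave out every lost region, so stability of rank was not shown. Lost CTCF regions also lay at gene ends, H3K27ac and the longer Matrin 3 list less often than regions called in all libraries. A gap particular to SATB1 was therefore not shown.

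**Figure D3:**
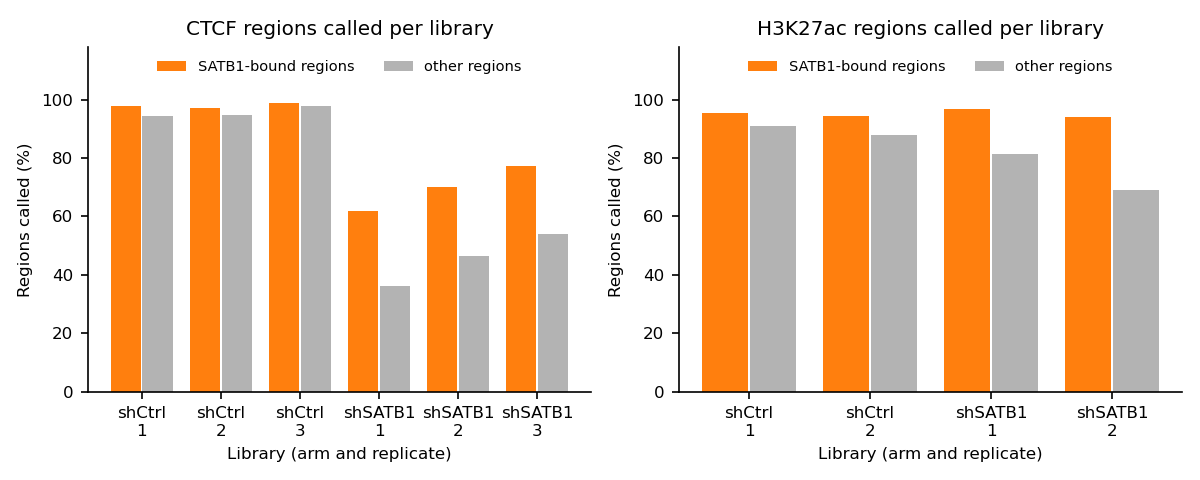
Share of regions called per library (y axis, percent) for CTCF (left) and H3K27ac (right), with SATB1-bound regions in orange and other regions in grey; each pair of bars is a library. In the CTCF shSATB1 libraries the orange bars lie 24.2 points above the grey ones on average, against 2.22 points in shCtrl.

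H3K27ac regions differed between the arms in both directions. Peaks numbered 17502 ± 511 (SD, n = 2) in shCtrl and 16949 ± 1381 (n = 2) in shSATB1 (exact permutation p = 1), 3.16% fewer, covering 52.9 ± 1.28 and 43.8 ± 3.90 Mb (exact permutation p = 0.333, the smallest that 2 against 2 allows). Without shSATB1 replicate 2 the difference was −2.42%, that is, more peaks in shSATB1; without shSATB1 replicate 1 it fell by 8.74%, and without shCtrl replicates 1 and 2 by 1.12% and 5.12%. Of 20526 merged regions, 12261 (59.7%) were called in all 4 libraries, 1221 in both shCtrl and no shSATB1 library, and 537 in both shSATB1 and no shCtrl library. The other splits of the 4 libraries gave 420 and 102, and 140 and 267. Lost and gained regions numbered 2008 and 948 without shCtrl replicate 1, 2383 and 808 without shCtrl replicate 2, 2437 and 1011 without shSATB1 replicate 1, and 1591 and 1730 without shSATB1 replicate 2. They numbered 1440 and 1015 in windows on the peak maxima, and 6314 and 1784 in bins.

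Gained H3K27ac regions carried SATB1 far more often than lost ones. SATB1 overlapped 226 of 537 gained regions (42.1%, 95% interval 38.0 to 46.3) and 157 of 1221 lost regions (12.9%, 11.1 to 14.9), a difference of 29.2 percentage points (p = 1.03e-39, Fisher's exact test over regions, which are not replicates). This comparison was not in the plan. Without shSATB1 replicate 2 the difference was 12.8 points, and without shSATB1 replicate 1 it was 15.8. Matrin 3 was also more frequent at gained regions (54.6% against 38.8%, longer list), while CTCF was less frequent (36.3% against 43.2%). Regions called in all 4 libraries overlapped SATB1 at 63.1%.

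**Figure D4:**
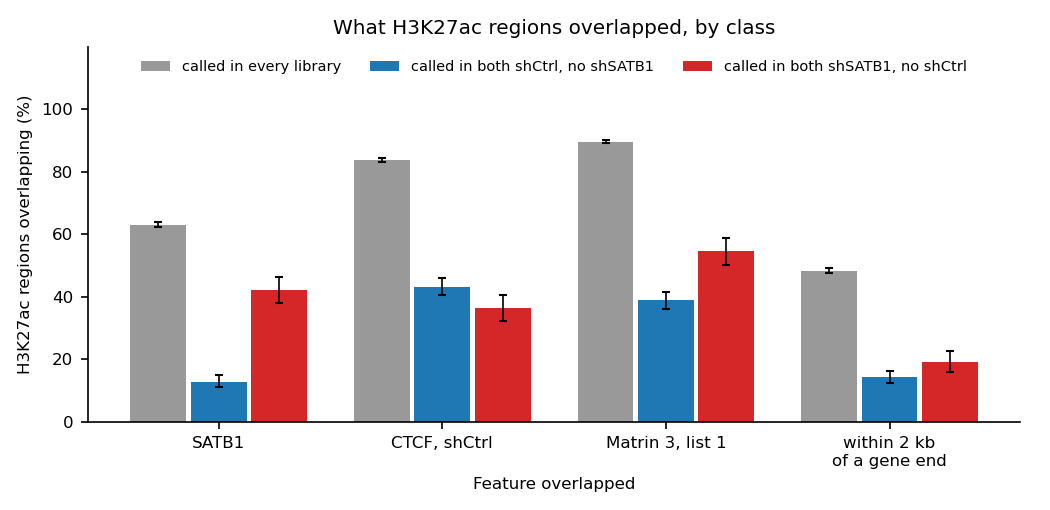
Share of H3K27ac regions (y axis, percent) that overlapped SATB1, CTCF, Matrin 3 or gene ends, for regions called in every library (grey), lost (blue) and gained (red); error bars are 95% Wilson intervals. The SATB1 share is 42.1% among gained and 12.9% among lost regions.

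The highest-ranked lost H3K27ac regions lay at an end of SLC22A16, a carnitine transporter gene (chromosome 6, 110473620 to 110476213, percentile 85.0 ± 2.89, SD, n = 2), 309 kb from BRD1 (chromosome 22, 49460978 to 49464647, 82.6 ± 6.58) and inside SH3KBP1 (chromosome X, 19565544 to 19567508, 79.0 ± 2.34). Others lay 36.9 kb from LOC124901165, 281 kb from TBC1D22A, 182 kb from EBF1, 26.1 kb from KLF15 and 9.19 kb from LY6H. The rest were inside NR5A2 and CRACD. The highest-ranked gained regions lay inside NLRP4 (chromosome 19, 55843077 to 55845127, 75.4 ± 3.12) and 32.9 kb from ARID5B (chromosome 10, 62129796 to 62134843, 71.3 ± 6.00), a regulator linked to T cell leukaemia. Regions 50.7 kb from RAP2B, 93.2 kb from UBE2E2 and 11.7 kb from RTL3 followed. So did regions inside SARDH, RPS6KA2, F13A1 and TMEM164 and at an end of PCYT1A.

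At gene ends, 169 genes lost H3K27ac and 100 gained it. Listed genes that lost it were LYL1, a leukaemia oncogene, and the receptor genes CCR4 and IL4R; BPTF, a chromatin remodeller, gained it. Cytokine and receptor genes had 13 members with H3K27ac in each shCtrl library and 10 in each shSATB1 library, while T cell receptor signalling averaged 16.5 in both arms and B cell markers 5. No list passed for loss of H3K27ac; cytokine and receptor genes alone had an unadjusted p under 0.05 (2 of 12 lost against 2.16% of the others, p = 0.0271, adjusted p = 0.460, Fisher's exact test).

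SATB1-bound H3K27ac regions were called at 94.9% ± 0.691 (SD, n = 2) in shCtrl and 95.4% ± 2.09 in shSATB1, while other regions were called at 89.4% ± 2.02 and 75.1% ± 8.72. The gap was 5.53 ± 1.33 points in shCtrl and 20.2 ± 6.63 in shSATB1, over 8905 SATB1-bound and 8275 other regions (exact permutation p = 0.333, smallest possible). Within deciles of rank it was −1.48 ± 0.0697 and 5.68 ± 1.53. The difference of the gaps, 14.7 points, was 5.65 without shCtrl replicate 1 and 6.99 without shCtrl replicate 2.

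Matrin 3 sites called in both of its lists mostly carried SATB1. Of the 1691 regions called in both Matrin 3 lists, 86.8% (95% interval 85.1 to 88.3) overlapped SATB1, against 1.48% ± 0.283 after shifts (permutation p = 0.00990). The longer list overlapped SATB1 at 45.6%, H3K27ac at 64.2% and CTCF at 73.4%. The shorter list overlapped the single SATB1 lists at 71.9% and 71.1%. It overlapped the single CTCF shCtrl lists at 78.1% to 79.0% and the H3K27ac shCtrl lists at 74.0% and 72.6%. High overlap of that list was therefore not particular to SATB1. Overlap of the 1691 regions with CTCF and H3K27ac was not computed. The shorter list overlapped the longer at 82.4%, and the lists differ in length too much for a spread between them to be given.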

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

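The tests of list length, peak width, rank and shared starts were chosen after the results were seen. Those of gene-end distance, peak strength (as within-list percentile) and peaks with high signal were set before their values were seen. Peaks outside the chromosomes analysed drew attention: 112 lay on alternate contigs, in 13 of the 14 lists.

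The loss of 7747 CTCF regions has a technical candidate, lower depth or yield in the shSATB1 libraries. With all lists cut to equal length, 598 regions were lost and 214 gained, so most of the count went with list length. Cutting the lists does not tell lower depth from lower occupancy. Lost regions came from the low end of the lists: 0.405% of the 7662 shCtrl regions above the 75th percentile were lost, against 74.3% of the 4527 at or below the 25th, which is consistent with that explanation. Windows of fixed width on the peak maxima gave 7528 lost regions. A region lost at full width already holds no shSATB1 peak, so narrower windows cannot decide whether wider shCtrl peaks play a part. Of the 10 splits of the 6 libraries, 1, the real one, gave as many, with 7750 regions in both directions against 71 in the highest other split; with equal lists it was 812 against 103, and for genes 1714 against 16, also 1 split each, and 10 splits are too few for a share under 0.05. A change of CTCF occupancy on knockdown stays open as untested, since library depth was not given in the sources used here.

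The higher SATB1 share of gained than of lost H3K27ac regions was not explained by list length, gene ends or within-list percentile. With equal list lengths the difference was 29.2 percentage points, away from gene ends 30.0, and weighted to equal percentile 28.7, against 29.2 as reported. Percentiles came from the shSATB1 lists for gained and from the shCtrl lists for lost regions. The mean lowest total signal was 4440.5 and 6744.5 in those lists, so equal percentile need not be equal signal. Differences in signal and in where calling stopped were therefore not tested. The other splits of the 4 libraries gave differences of 3.98 and 2.37 points, but 3 splits are too few for a share under 0.05. An effect of the knockdown and a difference between the H3K27ac arms in signal from open chromatin were not tested, and both stay open.

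The SATB1 lists shared 40.8% of exact peak starts, which is consistent with reads shared between the deposited lists. Tn5 cutting the same positions in separate libraries is argued against, since the highest share of any other pair was 1.03%. Few fragments per peak is argued against too, since peaks above the 75th percentile in both lists still shared 37.7%. Both SATB1 lists also had a lowest total signal of 4075, a median total signal of 6984 and a median maximum signal of 16. Whether and how reads were shared stays open, and no biological explanation was tested.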

How the results depend on the processing

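The lists near a peak, the equal-length count of genes and the alternatives for gained against lost H3K27ac regions were chosen after seeing the data. Of 163 alternative values, 123 kept their direction and side of the threshold or stayed within 1.5 times. Another 12 lost their call, 21 moved further and 7 turned direction. Exact tests that cannot pass 0.05 say nothing about stability. Nor do the stricter thresholds on peak number, which set 1 limit on unscaled signal of both arms, or region counts that the block cannot change. Leaving out 1 SATB1 list says little too, since those lists shared 40.8% of exact peak starts. CTCF regions lost and gained were 598 and 214 with equal list lengths, 33277 and 9 in bins of 1 kb, and 422 gained with windows on the maxima; leaving out a library gave 7975 to 10317 lost and 3 to 14 gained. H3K27ac regions lost and gained were 6314 and 1784 in bins, and 1015 gained with windows; leaving out a library gave 1591 to 2437 and 808 to 1730. Bins count length, so wide regions count many times. Leaving out a library loosens the rule of every library of an arm and none of the other, so those counts tend to rise. The causes of the other changes were not tested. CTCF loss at gene ends was 325 genes with equal lists. SATB1 regions fell to 6651 with the peaks above each list's median maximum, by construction. Matrin 3 regions were 2105 to 24566 in single lists. H3K27ac peaks were 3.16% fewer in shSATB1; leaving out a library gave −2.42% to 8.74%, the negative value without shSATB1 replicate 2. The CTCF rank difference, 0.0999 points, ranged from −1.27 to 0.0204 without single libraries (−0.498, −0.371, −0.824 and −0.786 in others). With genes carrying H3K27ac as background, 0 of 17 lists passed by Fisher's exact test (the protocadherins and others had no member to test), and the apoptosis list turned direction (adjusted p = 1). Replicate numbers did not pair the CTCF samples (correlation of same-numbered deviations −0.0435, 0.00481 and −0.0664). With the replicate number as a block, CTCF peaks were 44.3% fewer (p = 0.25, exact), the SATB1-bound gaps differed by 21.96 points (p = 0.25, exact) for CTCF and 14.7 points (p = 0.5, exact) for H3K27ac, and the region counts stayed at 7747, 3, 1221 and 537 by construction, so the block changed no call. The planned motif alternatives were not run, since genome sequence was not used here. Unknown depth limits each comparison of call counts between arms.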

Other observations

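The tests behind the values in this part were chosen after the results were seen. Only the 5 widest H3K27ac peaks of each library were listed, so a domain not given for a library is not shown to be absent there, and widths were not compared between arms. The widest H3K27ac peak of each library lay over CDK6, a cell cycle kinase gene. It spanned 115.0, 115.2, 116.8 and 99.7 kb in the shCtrl and shSATB1 libraries in turn, but not over the same stretch. In shSATB1 replicate 1 it covered 92725092 to 92841909, where shCtrl replicate 1 had separate peaks of 59.85 and 61.8 kb. At the stretch of the other libraries, shSATB1 replicate 1 had a peak of 99.8 kb (92608843 to 92708610). ETV6, a haematopoietic regulator, held a domain of 76.4 and 67.3 kb in the shCtrl lists and 54.2 kb in shSATB1 replicate 2. A domain of 58.6 kb in shCtrl replicate 1 lay 949 kb from BCL11B on chromosome 14 (98161634 to 98220246), and domains of 54.2 and 52.2 kb were there in the shSATB1 lists.

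Several gene-rich stretches held no peak in any of the 14 lists. On chromosome 6, 137 protein-coding genes between 28475042 and 32622338, from GPX6 to HLA-DRB1, had none, and 35 more between 32623391 and 33511412. On chromosome 17, 55 genes between 35765989 and 38852304 had none. Whether reads can be placed uniquely in these stretches was not tested, so an empty stretch is not evidence that nothing was bound.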
